A study of Homo sapiens with 14 samples.

How the data were processed

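HEK293 cells were treated with AcIm, AcIN3, NAIN3 or DMSO, and per the labels ribosomal and polyadenylated RNA were profiled in 14 samples, 2 biological replicates for each of 7 groups. Replicate values were not analysed here, so 3 groups (AcIm, AcIN3 and NAIN3 on ribosomal RNA) have values, given as means. The DMSO and polyadenylated RNA groups have no values here. The authors' mean R-score per nucleotide, a score from 0 to 1, was used as deposited. The submitters' processing notes name Bowtie2 and the build GRCh38, and give no version. The formula of the R-score, the treatment of the DMSO background, filters on depth and the reference sequence are not given in the sources used here. All deposited scores fell on steps of 0.0005, as means of a pair of values with 3 decimals would, and between 42.5% and 56.5% of values per profile lay on odd steps, which such a mean gives only where the replicates differ.

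These steps bear on the measurements in several ways. A score capped at 1 and floored at 0 loses order at both ends, and a nucleotide that stops reverse transcriptase without any reagent can affect a score that is set against DMSO. Averaging removes the spread between replicates, so no replicate error, p-value across replicates or leave-one-out value could be given. The depth is unknown, and a score of 0 may be a low or an uncovered signal. Reads of rRNA gene copies cannot be told apart, so the scores describe the rRNA pool.

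From the scores, percentile ranks (ties averaged) were taken within each rRNA and reagent. Highly reactive nucleotides were the top 10% by score, with ties ordered by position. For each of 3 pairs of reagents and 2 rRNAs, Spearman's rho and Pearson's r across nucleotides and the count of shared top nucleotides were computed, 6 correlations in all. Opposed nucleotides were those in the top 10% of one reagent and below percentile rank 50 in the other. The share of top nucleotides was compared in consecutive windows of 100 nt. As a description of these profiles, each value was set against all circular displacements of one profile along the rRNA, 1832 in 18S and 5033 in 28S. Displaced profiles are uncorrelated, so for opposed nucleotides and windows this reference only restates the correlation. These replaced the 10000 random displacements first planned, since no more distinct ones exist. Intervals for correlations and medians came from 1000 resamples of 50-nt blocks, and those for shares are exact Clopper-Pearson 95% intervals. Lists of ribose-methylated, base-modified and functional nucleotides, written from general knowledge in the numbering of the mature human rRNAs, were fixed before the data were examined, and each list was set against 10000 random lists. They were to be used only where the base in the rRNA sequence matched. No rRNA sequence was used here, so the match was not made, the random lists were not matched on base, and the numbering rests on the equal lengths of the profiles and the listed genes. For functional nucleotides the mean rank in a window of 5 nt on each side was also compared with all such windows.

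Base preference, predicted base pairing, GC-rich segments and the sarcin-ricin loop, all planned, need a sequence and were left out. Nucleotides named in the text followed a rule fixed before the data were examined. For each rRNA and pair they were the 5 with the largest rank difference in each direction among the top 10% of the higher reagent. Further nucleotides were the 5 highest scores of each reagent and rRNA, every member of the functional lists, the 3 windows with the largest difference per pair (windows tied with the last are given too), and the 3 highest ribose-methylated sites per reagent. The bound on replicates, the nucleotides at 1 in all reagents, the neighbours of opposed and of decoding-centre nucleotides, the groups of opposed nucleotides (gaps of at most 10 nt), their position along the rRNA and the rank differences over functional lists were examined after the data were seen. For the bound, a mean m of 2 replicates within 0 to 1 places each of them between 2m − 1 and 2m.

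The procedures were tested on simulated data. Of 40 opposed nucleotides planted among 1833 in the 18S profile 39 were recovered, and of 40 planted among 5034 in the 28S profile 40 were recovered, with no others called. The second simulated profile was otherwise a close copy of the first, so this run checked only the code. It could not show how many opposed nucleotides noise alone gives where profiles correlate as weakly as those of AcIm and NAIN3. Listed sites lowered on purpose fell at percentile 0 of random lists in both rRNAs. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The alternatives tried were other limits for the top (5% and 20%), leaving out 50 nt at each end, other windows, Pearson's r, 5-nt means, a stricter low class, scaled scores, profiles moved by 1 nt and several sets of nucleotides left out.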

Results

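Acylation of RNA in HEK293 cells, a line derived from human embryonic kidney, was read out as reverse transcription stops on ribosomal and polyadenylated RNA. The acylating reagents transfer an acyl group to the ribose 2′-hydroxyl of nucleotides that they can reach and that are flexible, so a high score is taken to mark a nucleotide open to the reagent. The labels list 14 samples in 7 groups of 2 replicates, with 8 samples of ribosomal RNA and 6 of polyadenylated RNA. For ribosomal RNA the groups were acetylimidazole (AcIm) at 100 mM, a reagent labelled AcIN3 at 200 mM, NAI-N3, the azide-bearing nicotinic acid imidazolide (NAIN3), at 100 mM, and 10% DMSO as the solvent control, each for 10 min. AcIN3 is known here by that name only, so no structure is given for it. The series title sets out to profile RNA structure in crowded spaces, and the comparisons below ask where reagents that carry different acyl groups reached the same nucleotides of the mature ribosomal RNAs.

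The values analysed were R-scores between 0 and 1 for each nucleotide of 18S and 28S rRNA, given for AcIm, AcIN3 and NAIN3 as the authors' mean over the replicates. No replicate values, read counts or DMSO profile were analysed here, so the depth behind a score is unknown and no test against the spread between replicates could be made. AcIm and NAIN3 were used at the same dose and time, whereas AcIN3 was used at a higher dose. The deposited 18S profile covers 1869 nt, the length of all 5 copies of 18S rRNA genes listed for GRCh38.p14 (RNA18SN1 to RNA18SN5). The 28S profile covers 5070 nt, which is the length of RNA28SN5 alone among the 5 listed 28S copies, at positions 113348 to 118417 of a sequence with no chromosome assigned. RNA18SN5 lies on an unassigned sequence too, at positions 109078 to 110946. Each listed locus encodes a mature structural rRNA of the ribosome without a coding region. Scores were present for nt 7 to 1839 of 18S (1833 nt) and nt 7 to 5040 of 28S (5034 nt), which leaves 6 nt at the 5′ end and 30 nt at the 3′ end of each rRNA without a score.

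AcIN3 gave the highest typical scores on both rRNAs and NAIN3 the lowest. In 18S the median R-score was 0.118 for AcIN3 (95% block interval 0.106 to 0.129), 0.077 for AcIm (0.07 to 0.0835) and 0.0225 for NAIN3 (0.018 to 0.0265). In 28S the medians were 0.101 for AcIN3, 0.0655 for AcIm and 0.033 for NAIN3. NAIN3 left 8.67% of 18S nucleotides and 10.2% of 28S nucleotides at exactly 0, against 0.764% and 0.755% for AcIm and 3.27% and 1.37% for AcIN3. Scores of exactly 1 were as rare in every reagent, on 14 nucleotides of 18S for AcIm, 14 for AcIN3 and 16 for NAIN3, and on 30, 34 and 41 nucleotides of 28S. Because doses and score ranges differed between reagents, the comparisons used ranks within a reagent and rRNA, and the 10% of nucleotides with the highest scores (183 in 18S, 503 in 28S) were taken as highly reactive. The intervals come from resampled stretches of 50 nt and cover variation along the rRNA, not between replicates.

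The AcIm and AcIN3 profiles ran closely together, and the NAIN3 profile departed from both. In 18S, Spearman's rho across nucleotides was 0.95 between AcIm and AcIN3 (0.94 to 0.96), 0.58 between AcIm and NAIN3 (0.50 to 0.65) and 0.58 between AcIN3 and NAIN3 (0.51 to 0.65). In 28S these were 0.88 (0.86 to 0.90), 0.62 (0.60 to 0.65) and 0.56 (0.53 to 0.59). Pearson's r ranged from 0.48 to 0.94 over the 6 correlations. Each rho lay above that of every circular displacement of one profile along the rRNA, of which the highest reached 0.25. Nucleotides are not independent replicates, and all reagents share the DMSO libraries, so part of each correlation may come from these.

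Highly reactive nucleotides were mostly shared between AcIm and AcIN3. In 18S, 145 of 183 (79.2%, Clopper-Pearson 95% interval 72.6 to 84.9%) were in the top 10% of both. Between AcIm and NAIN3 the shared count was 71 (38.8%, 31.7 to 46.3%), and between AcIN3 and NAIN3 it was 75 (41.0%, 33.8 to 48.5%), where unrelated lists would share 18.3. In 28S, AcIm and AcIN3 shared 375 of 503 (74.6%, 70.5 to 78.3%), AcIm and NAIN3 shared 257 (51.1%, 46.6 to 55.5%), and AcIN3 and NAIN3 shared 232 (46.1%, 41.7 to 50.6%), where unrelated lists would share 50.3. All displaced profiles shared fewer, at most 118 in 28S and 37 in 18S. These binomial intervals treat nucleotides as independent and do not cover replicate error.

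**Figure D1:**
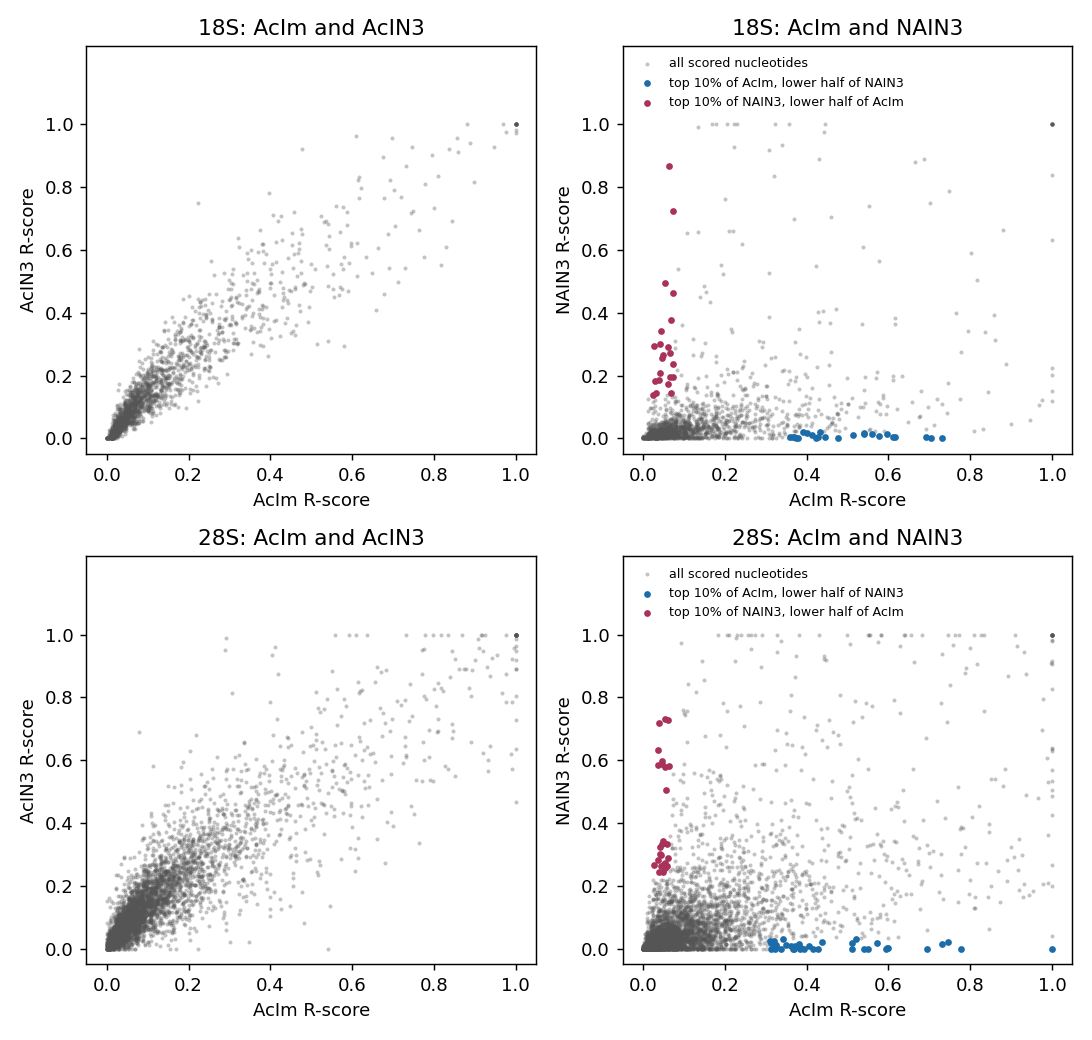
Each point is a nucleotide of 18S (upper panels) or 28S (lower panels), with the R-score of AcIm on the x axis and that of AcIN3 (left) or NAIN3 (right) on the y axis, all between 0 and 1. Coloured points are in the top 10% of one reagent and below the median rank of the other, 24 and 22 nucleotides of 18S and 37 and 28 nucleotides of 28S, and the AcIm and AcIN3 scores lie closer to a line (rho 0.95 and 0.88) than the AcIm and NAIN3 scores (0.58 and 0.62).

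At the matched dose and time, a minority of the nucleotides most reactive toward AcIm ranked low with NAIN3, and the converse also occurred. In 18S, 24 of AcIm's 183 top nucleotides (13.1%, 8.59 to 18.9%) fell below the median rank of NAIN3, and 22 of NAIN3's top nucleotides (12.0%, 7.69 to 17.6%) fell below the median rank of AcIm. In 28S the counts were 37 of 503 (7.36%, 5.23 to 10.0%) and 28 of 503 (5.57%, 3.73 to 7.95%). With only the lowest 25% taken as low, the counts were 14 and 4 in 18S and 24 and 1 in 28S. With the replicate bound given below, which only high scores can meet, they were 11 and 2 in 18S and 12 and 9 in 28S. Few of the NAIN3-high set thus ranked in AcIm's lowest 25% in 18S. The counts under the bound follow the score level, since the 18S top 10% began at 0.1385 for NAIN3 and 0.3595 for AcIm. They do not compare how far the replicates of each reagent differed. With the median as the limit, every displaced profile gave more opposed nucleotides. The means were 91.4 and 92.0 in 18S and 251 and 250.4 in 28S, which the positive correlations already require. In 18S, 17 nucleotides were high in both AcIm and AcIN3 and below the median of NAIN3, and 17 were high in NAIN3 and below the median of both others. In 28S these were 28 and 20. Scaled scores at least 0.5 apart, with no limit on the other reagent's rank, gave far more of the top nucleotides. For AcIm over NAIN3 and the reverse they were 111 and 92 of 183 in 18S and 202 and 215 of 503 in 28S.

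The 18S nucleotides with the widest lead of AcIm over NAIN3 were nt 1486 (R-score 0.730 for AcIm), nt 812 (0.704), nt 172 (0.477), nt 301 (0.423) and nt 231 (0.380), all listed at 0 for NAIN3. In 28S they were nt 914 (1.0 for AcIm and 0 for NAIN3), nt 2204 (0.777), nt 3004 (0.695), nt 1237 (0.594) and nt 4202 (0.551), again with NAIN3 at 0. AcIN3 was high at several of the same places, with 0.677 at nt 812, 0.651 at nt 172, 0.617 at nt 231 and 0.541 at nt 1486 of 18S, and 0.889 at nt 914 and 0.600 at nt 2204 of 28S. Its widest leads over NAIN3 also included nt 232 of 18S (0.609) and nt 552 (0.816), nt 3446 (0.731) and nt 544 (0.581) of 28S, again with NAIN3 at 0. The densest groups of AcIm-high, NAIN3-low nucleotides held 3 members each, at nt 168 to 172 and nt 216 to 231 of 18S and at nt 2739 to 2745 of 28S. In 18S, 17 of the 24 lay in nt 7 to 465, a stretch with 29.0% of AcIm's top nucleotides, and NAIN3 was at 0 in 19.2% of that stretch. In 28S the first stretch of the same relative length held 12 of the 37. Nt 172 of 18S, named here, is also listed as a ribose-methylated site (Um172), which lacks the free 2′-hydroxyl. Its scores may therefore not mark acylation there, though the listed position was not checked against the rRNA sequence.

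The reverse set was led in 18S by nt 548 (0.293 for NAIN3 and 0.028 for AcIm), nt 689 (0.139 and 0.0245), nt 742 (0.181 and 0.029), nt 1423 (0.145 and 0.0325) and nt 839 (0.301 and 0.0415). In 28S it was led by nt 4015 (0.267 and 0.0275), nt 4882 (0.632 and 0.0355), nt 265 (0.586 and 0.0355), nt 4990 (0.720 and 0.039) and nt 4950 (0.282 and 0.037). By scaled scores, nt 689 and nt 1423 of 18S fell short of a difference of 0.5, at 0.469 and 0.478. Against AcIN3, the leading NAIN3-high nucleotides were nt 393, nt 1423, nt 689, nt 742 and nt 328 of 18S, with NAIN3 scores from 0.139 to 0.341. In 28S they were nt 2207 (0.732 for NAIN3 and 0.0145 for AcIN3), nt 4853 (0.275 and 0), nt 4863, nt 894 and nt 2983. Many of the NAIN3-high, AcIm-low nucleotides directly followed a nucleotide in AcIm's top 10%, namely 9 of 22 (40.9%) in 18S and 14 of 28 (50%) in 28S. Among NAIN3's other top nucleotides 15.5% in 18S and 21.9% in 28S did so.

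**Figure D2:**
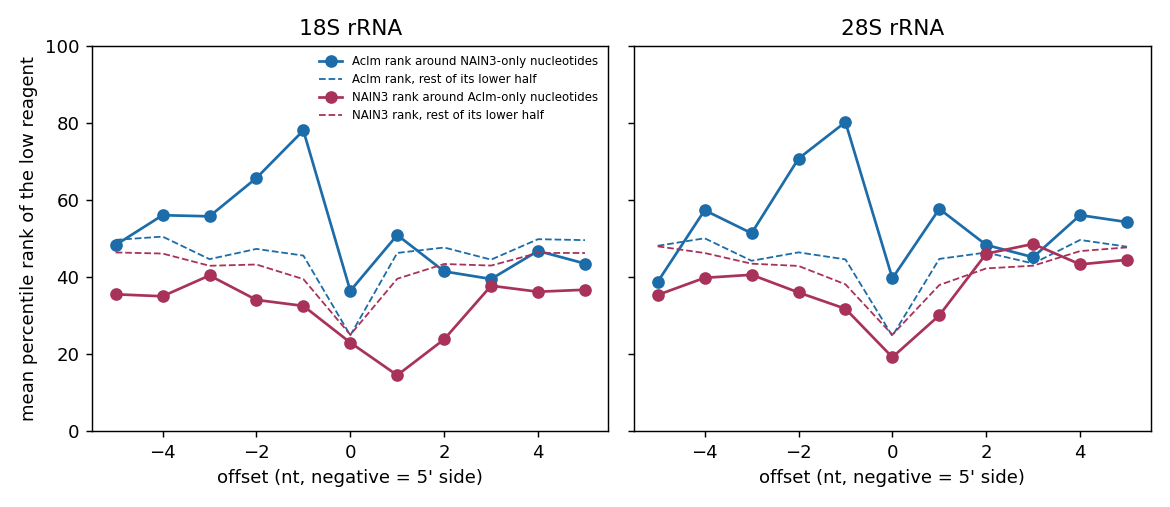
Mean percentile rank of the reagent in which opposed nucleotides are low, by offset in nucleotides from them (negative offsets on the 5′ side), for AcIm around NAIN3-high nucleotides (blue) and NAIN3 around AcIm-high nucleotides (red) in 18S (left) and 28S (right), with dashed lines for the other nucleotides below that reagent's median rank. The AcIm rank peaks 1 nt to the 5′ side, at 78.1 and 80.2, and the NAIN3 rank shows no such peak.

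Under the assumption that each replicate score lies between 0 and 1, a mean of 2 replicates bounds each replicate. Some means are then far enough apart that the replicates of the 2 reagents cannot overlap. The spread within a reagent may still exceed the difference. By this bound both AcIm replicates exceeded both NAIN3 replicates at 45 nucleotides of 18S (2.46%) and 55 of 28S (1.09%), and the reverse held at 19 (1.04%) and 43 (0.854%). For AcIN3 over NAIN3 the counts were 63 and 74, and for NAIN3 over AcIN3 they were 17 and 43. The bound compares scores, not ranks, and the higher mean must lie above the middle of the range from 0 to 1. In 18S, 91 nucleotides met this for AcIm, 129 for AcIN3 and 50 for NAIN3. In 28S, 233, 282 and 182 did so. The counts were not corrected for this, so a difference between directions may follow the score level of each reagent. Without any difference, 16.7% of the orderings of 2 against 2 replicates would separate in a given direction, and the bound shows only those separations that the means alone force. Of the AcIm-high, NAIN3-low nucleotides named above, nt 1486 and nt 812 of 18S and all 5 of 28S passed this bound, while nt 172, nt 301 and nt 231 did not. Of the named nucleotides that were high with NAIN3 and low with AcIm, 0 of 5 in 18S passed it and 3 of 5 in 28S did (nt 4882, nt 265 and nt 4990). Of those high with NAIN3 and low with AcIN3, 0 of 5 in 18S and 1 of 5 in 28S (nt 2207) passed it. Of those high with AcIN3 and low with NAIN3, 5 of 5 passed it in both rRNAs, nt 172 and nt 231 among them. The named NAIN3-high nucleotides of 18S scored at most 0.341, so they could not pass whatever their replicates were. Nt 4882 and nt 2207 of 28S directly follow nt 4881 and nt 2206, which scored 1 in all 3 reagents, as listed below.

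AcIm and AcIN3, used at different doses, rarely ranked a highly reactive nucleotide on opposite sides of the median. No top nucleotide of either in 18S fell below the median rank of the other (0 of 183, which allows up to 2.00%). In 28S, 3 of AcIm's 503 top nucleotides did so for AcIN3 and none of AcIN3's did so for AcIm. Scaled scores at least 0.5 apart were more frequent. For AcIm over AcIN3 and the reverse they were 10 and 3 of 183 in 18S and 54 and 42 of 503 in 28S. The widest AcIm leads in 28S were at nt 2203 (0.541 against 0), nt 4863 (0.348 against 0.0215) and nt 2262 (0.482 against 0.0825), and the widest AcIN3 lead was at nt 619 (0.690 against 0.078). Among the top nucleotides of 18S the widest gap in rank was 17.3 points, at nt 1348 (0.750 for AcIN3 and 0.223 for AcIm), followed by 16.2 points at nt 270 (0.581 for AcIm and 0.294 for AcIN3). Less reactive nucleotides could lie further apart, as nt 1824 of 18S did (ranks 72.9 for AcIm and 47.7 for AcIN3). By the replicate bound AcIm exceeded AcIN3 at 0 nucleotides of 18S and 2 of 28S, and AcIN3 exceeded AcIm at 1 and 6.

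All 3 reagents were dense at nt 2201 to 2300 of 28S, where 21% of nucleotides were in the top 10% for AcIm, 26% for AcIN3 and 23% for NAIN3. The share of highly reactive nucleotides per 100 nt differed most between AcIm and NAIN3 at nt 901 to 1000 of 18S (17% and 8%), nt 1101 to 1200 (5% and 12%) and nt 701 to 800 (11% and 17%), tied with nt 1701 to 1800 (10% and 16%). In 28S it differed most at nt 2301 to 2400 (13% and 4%), nt 4401 to 4500 (9% and 1%) and nt 1701 to 1800 (9% and 15%), tied with nt 3501 to 3600 (14% and 20%). Between AcIN3 and NAIN3 the widest gaps were at nt 901 to 1000 (18% and 8%), nt 701 to 800 (8% and 17%) and nt 401 to 500 (14% and 7%) of 18S, and at nt 3501 to 3600 (7% and 20%), nt 3001 to 3100 (29% and 19%) and nt 2301 to 2400 (13% and 4%), tied with nt 3301 to 3400 (9% and 18%), of 28S. AcIm and AcIN3 differed most at nt 3001 to 3100 of 28S (15% and 29%), nt 801 to 900 (13% and 5%) and nt 3501 to 3600 (14% and 7%), tied with nt 3101 to 3200 (18% and 11%), and in 18S by at most 5 percentage points, at nt 801 to 900, nt 1101 to 1200 and nt 1301 to 1400. The largest gap lay at the 24.9th percentile of displaced profiles for AcIm and NAIN3 in 18S and at the 0.795th percentile in 28S, and at no pair above the 36.8th percentile. With the top 20% the widest gap of AcIN3 and NAIN3 in 18S was 20 percentage points, above 98.1% of displaced profiles. Displaced profiles are uncorrelated and give wider gaps by construction, so these percentiles do not show whether a region differed between reagents.

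**Figure D3:**
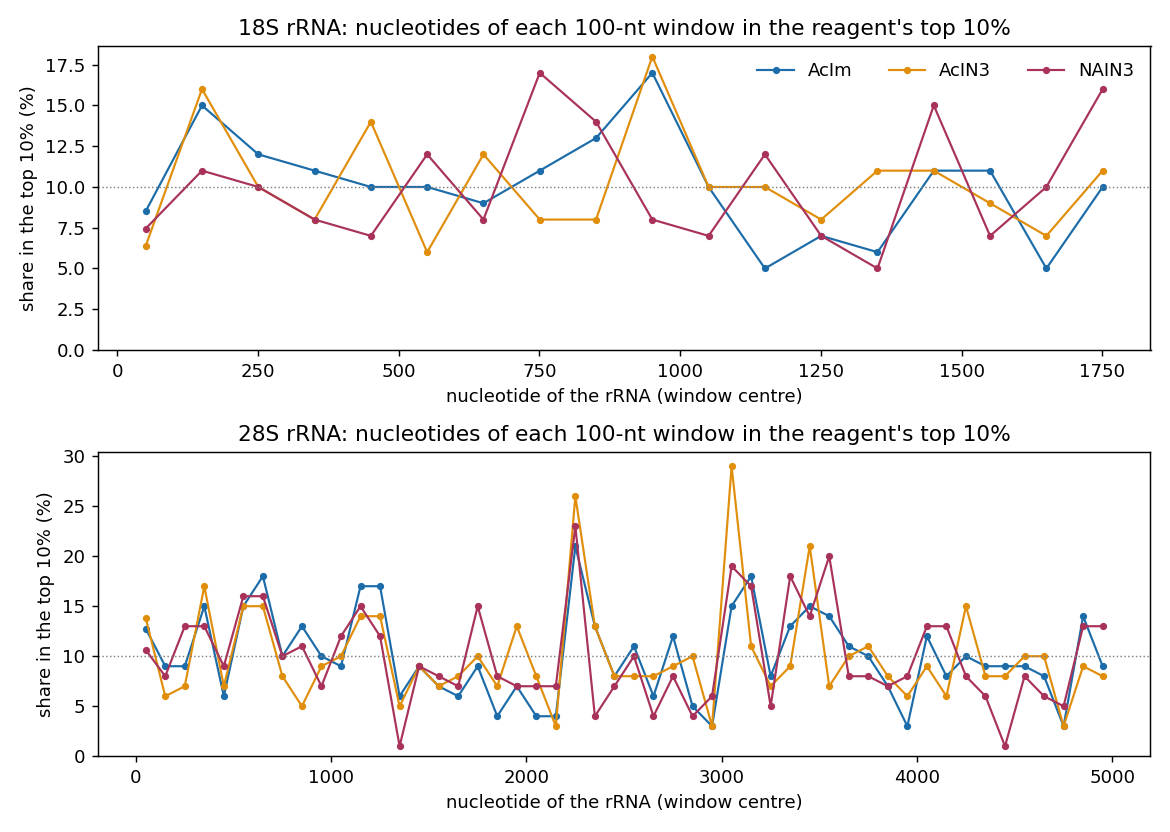
Lines give, for each 100-nt window of 18S (upper panel) and 28S (lower panel), the percentage of nucleotides in the top 10% of AcIm, AcIN3 or NAIN3, against the window's centre in nucleotides; the dotted line marks 10%. Windows hold at least 50 scored nucleotides, and a reader should see the common peak of all reagents at nt 2201 to 2300 of 28S (21%, 26% and 23%), the widest AcIm and NAIN3 gap of 18S at nt 901 to 1000 (17% and 8%) and the 29% share for AcIN3 at nt 3001 to 3100 of 28S.

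In the decoding centre of the small subunit, the nucleotides that monitor the pairing of codon and anticodon were among NAIN3's most reactive and not among those of AcIm or AcIN3. Nt 1825 scored 0.495 with NAIN3 (percentile rank 97.3), 0.0545 with AcIm (37.8) and 0.083 with AcIN3 (38.1). Nt 626 scored 0.195 with NAIN3 (92.9), 0.067 with AcIm (44.8) and 0.180 with AcIN3 (65.9). Nt 1824 scored 0.139 with NAIN3 (90.1), 0.166 with AcIm (72.9) and 0.111 with AcIN3 (47.7), so its score was not higher with NAIN3 than with AcIm, only its rank. None of these 3 nucleotides passed the replicate bound, so each NAIN3 value could come from a single replicate. The neighbours nt 1823 and nt 1826 ran the other way, with 0.461 and 0.383 for AcIm against 0.0495 and 0.077 for NAIN3. The listed sequence positions could not be checked against the rRNA sequence, which was not used here.

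Around the P site, nt 1639, a methylated guanosine, ranked at 84.7 with AcIm, 81.3 with AcIN3 and 92.1 with NAIN3, and nt 1701 ranked at 52.2, 51.9 and 73.4. In the peptidyl transferase centre of 28S, nt 4397 had ranks of 45.1, 47.4 and 76.9, and nt 4531 was high in every reagent (0.617, 0.674 and 0.454). In the A loop, which holds the end of the aminoacyl-tRNA, nt 4498 had ranks of 8.74, 17.2 and 35.5, and nt 4499 had ranks of 67.8, 82.6 and 71.8. The 11-nt windows around all these nucleotides had mean ranks between the 29.1st and 89.3rd percentiles of all such windows, apart from those around nt 1248 (94.3rd to 97.4th). Taken as a list, the 10 functional nucleotides had a mean rank of 82.5 with NAIN3, above 100% of random lists, against 61.1 with AcIm (88.3%) and 62.9 with AcIN3 (92.2%). Their windows had mean ranks of 62.9 with NAIN3 (above 99.5% of random lists), 54.7 with AcIm (87.4%) and 54.3 with AcIN3 (84.7%). Some listed nucleotides are adjacent and some windows overlap, which random lists do not copy. The list also holds nt 1248 and nt 4531, which is next to nt 4530, described below as blocks to reverse transcription. It was not screened for ribose-methylated nucleotides.

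Nucleotides whose natural base modification blocks reverse transcriptase were near the top of every profile. Nt 1248 of 18S, a hypermodified uridine of the P site, and nt 1322 of 28S, a methyladenosine, scored 1.0 with AcIm, AcIN3 and NAIN3. Nt 4530 of 28S, a methyluridine next to nt 4531, scored 0.852, 0.923 and 0.541. The dimethyladenosines at nt 1850 and nt 1851 of 18S, and the modified cytidine at nt 1842, lay in the stretch without scores. Base-modified nucleotides that do not block the enzyme ranged widely, from the acetylcytidine at nt 1337 (ranks 32.8, 57.0 and 73.9 for AcIm, AcIN3 and NAIN3) and the methyladenosine at nt 1832 (9.22, 5.48 and 17.0) to nt 3782 (60.6, 64.3 and 41.4), nt 4220 (50.1, 67.1 and 47.4) and nt 4447 (1.13, 0.695 and 27.4) of 28S, and the highest of them was nt 1639 with the ranks given above. A score of 1 in all 3 reagents occurred at 7 nucleotides of 18S (nt 103, 360, 541, 554, 1247, 1248 and 1767) and 10 of 28S (nt 121, 1135, 1254, 1322, 1766, 2206, 3352, 3456, 3457 and 4881).

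Among the first nucleotides at the ceiling of each reagent, NAIN3 reached 1 at nt 74, nt 75, nt 283 and nt 285 of 18S, where AcIm scored from 0.168 to 0.358. AcIm and AcIN3 both reached 1 at nt 485 and nt 226 of 18S, where NAIN3 scored 0.152 and 0.840. AcIm reached 1 at nt 367 of 18S, where AcIN3 scored 0.973 and NAIN3 0.117. AcIN3 reached 1 at nt 448 of 18S, where AcIm scored 0.969 and NAIN3 0.105. In 28S, AcIm and AcIN3 both reached 1 at nt 620 (0.484 for NAIN3) and nt 638 (0.828), AcIN3 did at nt 120, nt 467 and nt 624, AcIm and NAIN3 did at nt 566, and NAIN3 did at nt 134, nt 666 and nt 895. Ties at 1 were ordered by position, so these are the most 5′ of the nucleotides at the ceiling.

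Ribose-methylated nucleotides, which lack the free 2′-hydroxyl, had median ranks within those of random lists in every profile. The median percentile rank of the 41 listed sites in 18S was 49.9 for AcIm, 49.5 for AcIN3 and 45.0 for NAIN3, at the 48.0th, 46.3rd and 22.5th percentiles of 10000 random lists of the same size. For the 65 sites in 28S the medians were 45.8, 51.4 and 44.3, at the 21.9th, 57.0th and 15.6th percentiles. Above the median rank lay 20, 20 and 18 of the 41 sites and 31, 37 and 24 of the 65. The lowered median that a missing hydroxyl would predict was thus not seen at the listed positions. At their 5′ neighbours the median was lower for AcIm (42.6 in 18S and 36.9 in 28S) and AcIN3 (48.9 and 48.8). For NAIN3 it was higher there (50.6 and 55.6). Whether the unchecked numbering or stops that do not need acylation contribute was not tested. The highest sites in 18S were Um172, Gm509 and Am668 for AcIm (scores 0.477, 0.374 and 0.309), Um172, Am668 and Gm867 for AcIN3 (0.651, 0.491 and 0.383) and Gm867, Gm509 and Cm517 for NAIN3 (0.231, 0.195 and 0.171). In 28S they were Am1323, Gm4042 and Gm4228 for AcIm (0.464, 0.452 and 0.366), Gm4042, Gm4623 and Gm3744 for AcIN3 (0.649, 0.514 and 0.491) and Gm4623, Gm4042 and Gm3744 for NAIN3 (0.341, 0.331 and 0.264). Am1323 directly follows the reverse-transcription block at nt 1322. Um172 is nt 172, named above as high with AcIm and AcIN3 and at 0 with NAIN3. The random lists were not matched on base. With the top 20% as the limit, 9.23% of the 28S sites were in the top of NAIN3 where 20% would be by chance (exact binomial test, two-sided p = 0.0291, unadjusted), and the same test passed for no other profile or limit.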

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

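Tests on the replicate bound, NAIN3 zeros, neighbours of top nucleotides, the 5′ stretch of 18S, nucleotides at 1 in all reagents and the rank differences over functional lists were chosen after seeing the data. No paired analysis was possible because the values are means over the replicates, and for the same reason no replicate could be left out. Alternatives for base preference, predicted pairing and GC-rich segments were not run, since no rRNA sequence was used here, and random lists matched on base could not be drawn. Depth is unknown and sets no limit that could be computed. Over the alternatives, 11 of 12 medians, 31 of 39 correlations and 19 of 27 shared shares stayed within their interval, 64 of 98 opposed shares stayed within 1.5 times (or within the interval of 0), and 28 of 30 values of ribose-methylated sites and 9 of 17 of functional nucleotides stayed on the same side of their reference. Of the values for named nucleotides, 107 of 118 stayed close in rank or at least 0.5 apart in scaled score. Unless a construction shows it, the cause was not tested.

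AcIm and AcIN3 stayed the closest pair in both rRNAs under every alternative for the correlation. Pearson's r was 0.48 for AcIm and NAIN3, 0.48 for AcIN3 and NAIN3 and 0.94 for AcIm and AcIN3 in 18S. Means over 5 nt gave 0.49, 0.47 and 0.91 in 18S, and 0.70 for AcIm and NAIN3 and 0.84 for AcIm and AcIN3 in 28S. The NAIN3 median in 28S was 0.0405 without nucleotides at 0. With the top 20%, the shared share was 53.8% (AcIm and NAIN3) and 55.2% (AcIN3 and NAIN3) in 18S and 60.8%, 55.7% and 78.3% (AcIm and AcIN3) in 28S. With the top 5% it was 70.3% for AcIm and AcIN3 in 18S and 43.0% and 39.4% for AcIm and AcIN3 with NAIN3 in 28S. The largest window gap of AcIN3 and NAIN3 in 18S was 20 points with the top 20%, above 98.1% of displacements.

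The share of opposed nucleotides moved with the definition, which fixes part of it. Taking the lowest 25% as low gave 7.65% (AcIm over NAIN3), 2.19% (NAIN3 over AcIm), 7.65% (AcIN3 over NAIN3) and 3.28% (NAIN3 over AcIN3) in 18S, and 4.77%, 0.199%, 5.77% and 1.79% in 28S. Scaled scores at least 0.5 apart gave 60.7%, 50.3%, 56.3% and 49.2% in 18S and 40.2%, 42.7%, 48.7% and 45.9% in 28S, with 5.46% for AcIm over AcIN3 in 18S and 10.7% and 8.35% for AcIm over AcIN3 and the reverse in 28S. In 28S the top 20% gave 12.0%, 9.94% and, for NAIN3 over AcIN3, 12.9%, with 1.99% for AcIm over AcIN3, and the top 5% gave 4.78% (AcIN3 over NAIN3) and 4.38% (NAIN3 over AcIN3). Adding the replicate bound left 6.01% (AcIm over NAIN3), 1.09% (NAIN3 over AcIm) and 1.09% (NAIN3 over AcIN3) in 18S and 2.39%, 1.79%, 2.98%, 1.39% and, for AcIm over AcIN3, 0.199% in 28S. Without nucleotides beside an AcIm top nucleotide, 3.27% of NAIN3's top were opposed to AcIm in 28S, or 10 nucleotides.

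With the profile moved by 1 nt towards the 3′ end, the median rank of 28S ribose-methylated sites for AcIm was 36.9, below all but 1.42% of random lists. The mean AcIm rank of the functional nucleotides was then 68.4, above 98.1% of random lists. With the top 20%, 9.23% of 28S ribose-methylated sites were in NAIN3's top against 20% by chance (exact binomial p = 0.0291). The mean lead of NAIN3 over AcIm in the decoding centre was 13.9 rank points with the profile moved towards the 5′ end and 10.6 towards the 3′ end, and 20.8 and 14.4 over AcIN3, none beyond random lists. Over all functional nucleotides not beside a blocking site it was 15.4 and 8.09 over AcIm, and 10.3 over AcIN3 towards the 3′ end, each within the central 95% of random lists.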

Other observations

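The tests of the rank lead over functional nucleotides, of a displaced NAIN3 profile, of blocking modifications and of AcIm's density were chosen after their results were seen, and the other tests below after the patterns were seen. Over all 10 functional nucleotides NAIN3 ranked above AcIm at 8 and above AcIN3 at 7, with mean leads of 21.5 and 19.6 rank points, above 99.7% and 99.3% of 10000 random lists of the same size. Over those that do not lie beside a reverse-transcription block, NAIN3 ranked above AcIm at 8 of 8 and above AcIN3 at 7 of 8, the exception being nt 4499 of 28S. This limit was set after the results were seen, and it removes nt 1248 and nt 4531, where NAIN3 did not lead. The list was not screened for ribose-methylated nucleotides, which lack the free 2′-hydroxyl, so a lead may not mark acylation at each member. The mean lead was 27.0 rank points over AcIm, above 99.8% of random lists, and 24.7 over AcIN3, above 99.7%. Over all scored nucleotides, NAIN3 ranked above AcIm at 53.4%. The decoding centre contributed most, with mean leads of 41.6 over AcIm and 42.9 over AcIN3 from 3 nucleotides (99.7% and 99.9% of random lists). Nt 1824 and nt 1825 of 18S are adjacent, as are nt 4498 and nt 4499 of 28S. Random lists of single nucleotides do not copy this, so the percentiles in this paragraph may be too high. The P site, the peptidyl transferase centre and the A loop had leads over AcIm of 9.49, 15.3 and 15.4, none beyond 82.1% of random lists. With all profiles moved by 1 nt, the decoding-centre lead over AcIm was 13.9 or 10.6 rank points, within the range of random lists, and that over AcIN3 was 20.8 or 14.4, also within it. For the narrower list these moves gave leads of 15.4 and 8.09 over AcIm, above 95.9% and 81.3% of random lists, and of 17.7 and 10.3 over AcIN3, above 97.8% and 86.7%. No explanation was tested for this lead.

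Neighbouring nucleotides resembled each other more in NAIN3 than in the other reagents. The rank correlation between adjacent nucleotides was 0.47 in 18S and 0.52 in 28S for NAIN3, against 0.16 and 0.22 for AcIm and for AcIN3. The correlation at 3 nt exceeded that at 2 nt for AcIm (0.23 and 0.26 against 0.10 and 0.16) and for AcIN3 (0.24 and 0.27 against 0.11 and 0.18), but not for NAIN3 (0.30 and 0.28 against 0.31 and 0.32).

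NAIN3-high, AcIm-low nucleotides tended to sit directly 3′ of nucleotides that were high with both reagents, with mean ranks there of 78.1 in 18S and 80.2 in 28S for AcIm and 89.5 and 90.2 for NAIN3, against AcIm ranks of 50.9 and 57.7 at the 3′ neighbour. At the 5′ neighbour of NAIN3's other top nucleotides the mean AcIm rank was 54.4 and 65.4, and at that of NAIN3-high, AcIN3-low nucleotides the AcIN3 rank was lower, at 68.5 and 68.0. A displacement of the whole NAIN3 profile by 1 nt was argued against, since the correlation of AcIm with NAIN3 at that offset was at most 0.217, below the unshifted 0.58 and 0.62. A spread of NAIN3 signal to the 3′ neighbour of every strong nucleotide may contribute and cannot be told apart from local structure. This was examined among neighbours of AcIm's top nucleotides that lay below AcIm's median rank. Their mean NAIN3 rank on the 3′ side minus that on the 5′ side was -2.30 in 18S (-10.1 to 6.46) and 4.47 in 28S (-0.394 to 10.1). Some NAIN3-high, AcIm-low nucleotides directly followed one that scored 1 in every reagent. They were nt 361, nt 542 and nt 1768 of 18S and nt 2207 and nt 4882 of 28S. Whether a natural reverse-transcription block at the 5′ neighbour contributes there was not tested and stays open. A difference in which flexible nucleotides the larger acyl group reaches was not tested and stays open.

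Scores at natural reverse-transcription blocks ranked near the top in every reagent, at 1 for nt 1248 and nt 1322 and down to 0.541 (NAIN3) for nt 4530. The lowest percentile rank over the 3 scored blocking nucleotides and the reagents was 96.8, while the 6 scored base-modified nucleotides that do not block had a median rank of 48.7 over the reagents. This is consistent with stops that do not need acylation entering the score, a hypothesis in which a score of 1 shared by all reagents may mark a block rather than an open nucleotide. The stops in DMSO, which would decide it, were not analysed here, so acylation at these nucleotides stays open.

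AcIm-high, NAIN3-low nucleotides of 18S gathered near its 5′ end, with 17 of 24 (70.8%) in nt 7 to 465. More of AcIm's highest scores in that stretch are unlikely to account for this alone, since 10000 draws from AcIm's top nucleotides placed at most 15 there. The draws took single nucleotides as independent, whereas some of the 17 lie close together. The stretch was also picked from 4 after the data were seen, so the percentiles in this paragraph may be too high. NAIN3 scores of exactly 0 made up 19.2% of that stretch and 8.95%, 0.66% and 5.90% of the next 3 stretches of the same length. These zeros are unlikely to be the whole cause, since 13 of the remaining 18 lay there without them, above 100% of the draws. Lower NAIN3 scores throughout the stretch (median 0.014 against 0.0215, 0.03 and 0.0205) were removed by ranking NAIN3 within each of the 4 stretches, and 13 of 21 still lay there, above 99.9% of draws. Ranking removes a lower level but not a less reliable order among low scores, so weak NAIN3 signal there stays open. Without the stretch, rho with NAIN3 was 0.618 for AcIm and 0.633 for AcIN3, against 0.578 and 0.582 with it, within the intervals of the latter. Uneven NAIN3 depth within the stretch and a local closure toward NAIN3 in this part of the small subunit were not tested, and 28S showed no such gathering (12 of 37).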
